A study of Homo sapiens with 2 samples.

How the data were processed

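Small RNAs retained by an affinity resin were sequenced from MDA231 cells, the triple-negative breast cancer line also written MDA-MB-231. Per the labels' protocols, the long non-coding RNA MACC1-AS1 was made in vitro with T7 RNA polymerase as a fusion with MS2 hairpins. It was bound to amylose resin through a fusion of maltose-binding protein with the MS2 coat protein. Cell lysate was passed over the resin, the resin was washed, and bound complexes were released with maltose before RNA purification and miRNA sequencing. The bait library carried MACC1-AS1-MS2 as RNA substrate and the no-bait library had no RNA substrate, per the labels. Each group held 1 library, so no difference has a replicate check and no p-value was computed across miRNAs.

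For each library the authors deposited a whole-number count for each of 2588 mature miRNA names. They also deposited a normalized value, which is an RPM: it equalled the library's count divided by its total and scaled as RPM, with a largest deviation of 0.00994 RPM. BWA is named in the submitters' processing notes, with no version. The miRNA reference, genome build, adapter trimming, length filter and treatment of reads that match several miRNAs are not given in the sources used here. How reads shared by near-identical miRNAs were divided is therefore unknown, and the ratios of members of such families are uncertain. miRNA-seq reads without molecular identifiers also carry amplification and ligation preferences, which differ between sequences. A separate table of the authors' own comparison gives per miRNA a log2 fold change of bait over no-bait RPM and a p-value from a test that the sources used here do not name. In it a value of 0 RPM was replaced by 0.01, which was checked on 303 miRNAs.

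Counts were scaled by each library's total miRNA count, and the bait over no-bait ratio was computed per miRNA. Its exact conditional binomial 95% interval, like every interval and floor here, covers counting error only. A miRNA was tested if the libraries together held at least 30 counts. It was called higher at a ratio of at least 2, and lower at a ratio of at most 0.5, where the interval excluded 1. A miRNA with 0 counts in 1 library was given a ratio against a floor of 3 counts in that library, which is 2.87 RPM with bait and 11.1 RPM without. The interval of such a miRNA was computed from the 0 counts, and its bound can be less extreme than this ratio. Shares of a library have exact Clopper-Pearson 95% intervals. Total counts were 1047269 with bait and 269716 without, a 3.88-fold difference, so the no-bait library limits the precision of most ratios.

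Before the data were examined, 18 lists of miRNAs were fixed. They comprised the recalled partners of MACC1-AS1, the let-7, miR-29, miR-30, miR-15/16, miR-181 and miR-320 families, the miR-17-92 cluster with its paralogs, the miR-23-27-24 clusters, the group of miR-10, miR-99, miR-100 and miR-125, miRNAs of basal breast lines, epithelial miRNAs, tumour-suppressor miRNAs, blood cell miRNAs, liver, muscle and neural miRNAs, the 14q32 cluster, the 19q13 primate cluster, and entries overlapping other small RNAs. The median log2 ratio of each list with at least 3 tested members was placed among the medians of 10000 random lists of the same size, matched on deciles of mean abundance. A list stood apart below the 2.5th or above the 97.5th percentile. This percentile describes these libraries and does not depend on the scaling between them. For hairpins with both arms tested, the arm with the smaller sum of RPM was called minor.

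The miRNAs named in the text were chosen by a rule written at the same time. It took the 10 with the highest lower interval bound, the 10 with the lowest upper bound, the 5 most abundant in each library, the recalled partners, and per list up to 4 members with the highest summed counts. Other miRNAs that are named were chosen after their values were seen. Hairpin coordinates are those of GENCODE version 29 on GRCh38, matched by gene symbol. The build used by the authors is not given in the sources used here.

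Seed sites were searched in the annotated MACC1-AS1 transcript of 639 nt. Mature sequences were not among the deposited values. They were written from memory for 220 tested miRNAs, and all 220 were found in the hairpin sequence of GENCODE, which departs from the plan to take them from a file. The isoform and MS2 repeats of the bait itself were not analysed here.

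Alternative scalings were edgeR 4.0.16 TMM factors, DESeq2 1.42.0 median-of-ratios size factors, and totals without the 5 most abundant miRNAs. Further alternatives were minimums of 10 and 100 counts, no count filter with 0.5 counts added for list medians, the deposited RPM in place of the counts, an interval bound beyond 2-fold, and random lists without matching. Added after the data were seen were identical mature sequences counted once, the entries overlapping other small RNAs left out, and bait counts thinned to the no-bait total in 100 draws. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3. The calls were tested on simulated Poisson counts drawn from the real totals and mean abundances, and scaled with the known true factors. Of planted 4-fold increases 94.7% of 19 were called, and of planted 8-fold increases 100% of 22. Of planted 4-fold decreases 100% of 15 were called, and of planted 8-fold decreases 100% of 17. Of 157 unchanged miRNAs 0.637% were called, and the intervals covered 97.0% of 230 true ratios. These rates leave out errors of scaling and variation between libraries beyond counting, so they are not error rates of the real calls. The lists were tested on independent normal values instead of counts, and 7 of 100 unshifted lists stood apart.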

Results

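The deposited data are counts of mature miRNAs recovered from MDA231 breast cancer cell lysate on a resin carrying the MS2-tagged long non-coding RNA MACC1-AS1, and on the same resin without RNA. The comparison addresses which miRNAs associate with the tagged RNA. The control resin carried no RNA, neither an unrelated RNA nor the MS2 hairpins alone. A higher ratio with bait can therefore not be assigned to MACC1-AS1 rather than to the MS2 hairpins or to any RNA on the resin. The ratios compare shares of each library, with no scale for the total amount recovered. A gain of some miRNAs lowers the shares of others, so a lower ratio need not mean that less was recovered. The gene lies on chromosome 7 from 20141916 to 20153531 on the plus strand (ENSG00000228598.1, GRCh38), where the annotation gives it 4 exons. There were 2 libraries, 1 with bait (1047269 counts) and 1 without (269716 counts). All differences below compare these libraries and have no replicate check, and their intervals cover counting error only.

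Both libraries were dominated by the same few miRNAs. miR-100-5p was the most abundant in each, with 29.6% of counts with bait (95% interval 29.5% to 29.7%) and 45.3% without (45.1% to 45.5%). It is encoded in an intron of MIR100HG on chromosome 11 (122152229 to 122152308, minus strand). miR-21-5p, a miRNA raised in many tumours, took 16.7% with bait and 9.73% without. miR-92a-3p, a member of the miR-17-92 cluster, took 12.8% and 12.2%. The 10 most abundant names held 80.5% of the bait counts and 83.5% of the no-bait counts. At least 1 count was seen for 651 names with bait and 476 without, and for 412 names in both. When the bait library was thinned to the no-bait total it held 459 ± 8.32 names (SD over 100 random draws), so the larger number of names with bait went with its depth.

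The ratio spread widely around these abundant species. Of 231 tested miRNAs, 91 were at least 2-fold higher with bait and 62 at least 2-fold lower. Without a count filter 95 were higher and 100 lower of 715, so the excess of higher calls depended on the filter. miR-125b-5p rose from 4672 RPM without bait to 53091 RPM with it, 11.4-fold (10.7 to 12.0), and was the fourth most abundant miRNA there. miR-30a-5p was 6.27-fold higher (5.97 to 6.58). miR-222-3p, encoded on the X chromosome (45747015 to 45747124, minus strand) and typical of basal breast lines, was 5.01-fold lower with bait (4.87 to 5.15), falling from 40198 to 8028 RPM. miR-100-5p, miR-21-5p and miR-99b-5p passed neither rule, with ratios of 0.655, 1.72 and 1.17, but DESeq2 size factors put miR-21-5p past the higher rule at 2.30. The ratio of miR-92a-3p was 1.05, and its log2 value of 0.07 changed sign to -0.06 with totals that leave out the 5 most abundant miRNAs. The split of calls moved with scaling, since DESeq2 size factors gave 114 higher and 44 lower, or 72.2% higher against 59.5% in the main scaling. The median log2 ratio of tested miRNAs was 0.55 and shifted by 0.15 with TMM, 0.42 with DESeq2 and -0.13 without the 5 most abundant. Of the 62 lower calls, 54 were kept with TMM and 44 with DESeq2, and of the 91 higher calls 85 were kept without the 5 most abundant. Spearman's rho between the libraries was 0.660 across the 231 miRNAs, which are not independent replicates.

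**Figure D1:**
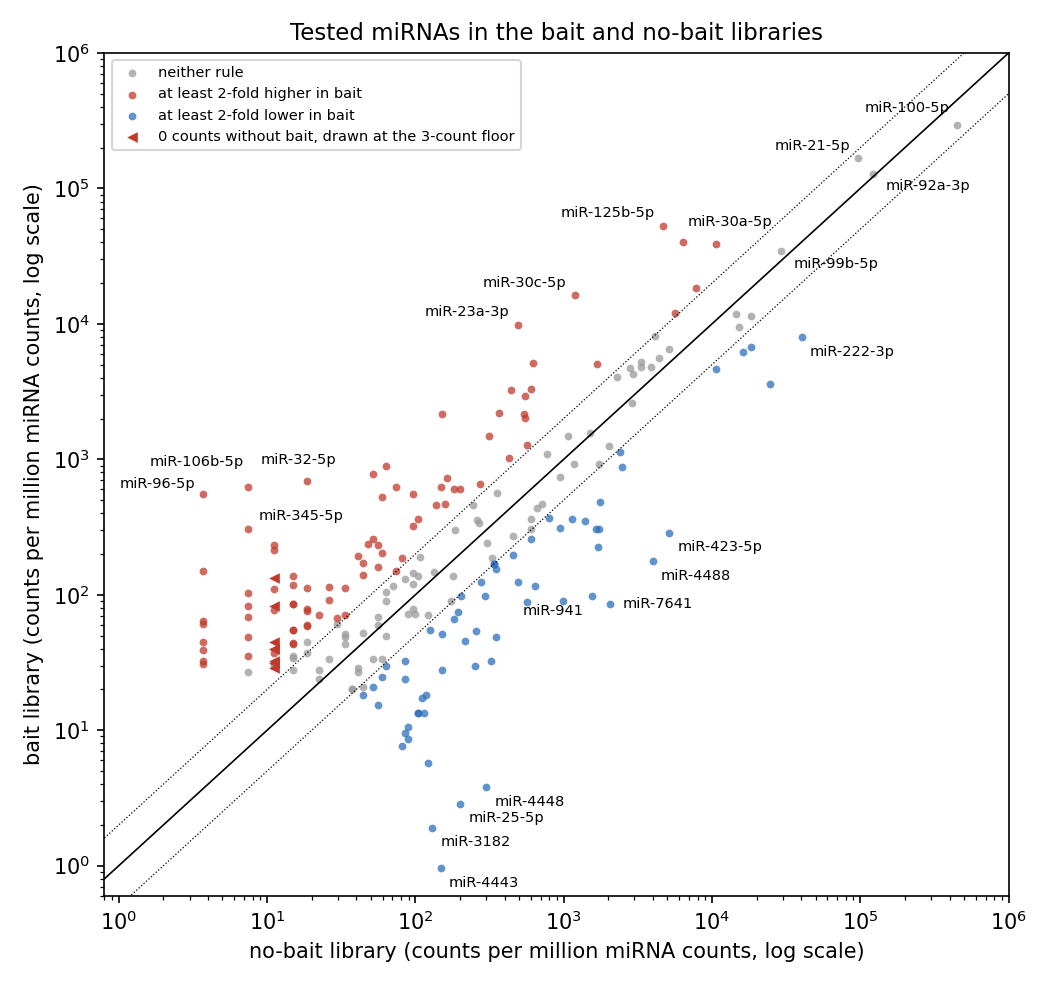
Each point is 1 of the 231 tested miRNAs, with its RPM in the no-bait library on the x axis and in the bait library on the y axis, both on log scales, with dotted lines at 2-fold. Red points are the 91 higher and blue points the 62 lower miRNAs under scaling by totals, and triangles mark the 8 miRNAs with 0 counts without bait, drawn at the floor of 3 counts.

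Among the miRNAs with the highest lower bounds, several had next to no counts without bait. miR-96-5p (chromosome 7, 129774692 to 129774769, minus strand) had 583 counts with bait and 1 without, a ratio of 150 with an interval of 26.8 to 5941. miR-106b-5p had 655 counts and 2 counts, a ratio of 84.3 (23.3 to 698). It lies in an intron of the replication gene MCM7 (chromosome 7, 100093993 to 100094074, minus strand). miR-32-5p, from an intron of TMEM245 on chromosome 9, had 723 and 5 counts, 37.2-fold (15.9 to 115). miR-345-5p had 323 and 2 counts, a ratio of 41.6 (11.4 to 345). miR-324-3p had 139 counts with bait and 0 without. Its ratio was 11.9 against the floor of 3 counts, and the lower bound of its interval was 9.58. Besides miR-125b-5p, deeper counts lay behind the ratios of miR-23a-3p, 20.2-fold higher (17.0 to 24.1) from 10330 and 132 counts, and miR-30c-5p, 13.7-fold higher (12.3 to 15.4) from 17076 and 320 counts. miR-30e-5p was 14.1-fold higher (10.4 to 19.8) and miR-218-5p, whose hairpins lie in introns of SLIT2 and SLIT3, was 15.0-fold higher (8.90 to 27.6).

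Of the 10 miRNAs with the lowest upper bounds, 3 belong to the fixed list of entries overlapping other small RNAs, namely miR-4488, miR-6087 and miR-664a-5p. miR-4488 fell from 1076 counts without bait to 185 with bait although the bait library was deeper, 22.6-fold lower (19.3 to 26.5). miR-7641, 1 of whose 2 annotated hairpins overlaps a 5S ribosomal RNA pseudogene on chromosome 14, was 23.9-fold lower (19.1 to 30.2). miR-423-5p was 17.9-fold lower (15.8 to 20.4) and miR-941, annotated in introns of DNAJC5 on chromosome 20, 15.95-fold lower (12.8 to 20.0). miR-664a-5p was 10.9-fold lower (8.62 to 14.003) and miR-6087 21.4-fold lower (8.84 to 62.4). The other entries of this set had 1 to 4 counts with bait. They were miR-4443 with 1 count against 40 (ratio 0.0064, 0.0002 to 0.038), miR-3182 with 2 against 35 (0.0147, 0.0017 to 0.0573), miR-25-5p with 3 against 54 (0.0143, 0.0029 to 0.0441) and miR-4448 with 4 against 81 (0.0127, 0.0034 to 0.0338).

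**Figure D2:**
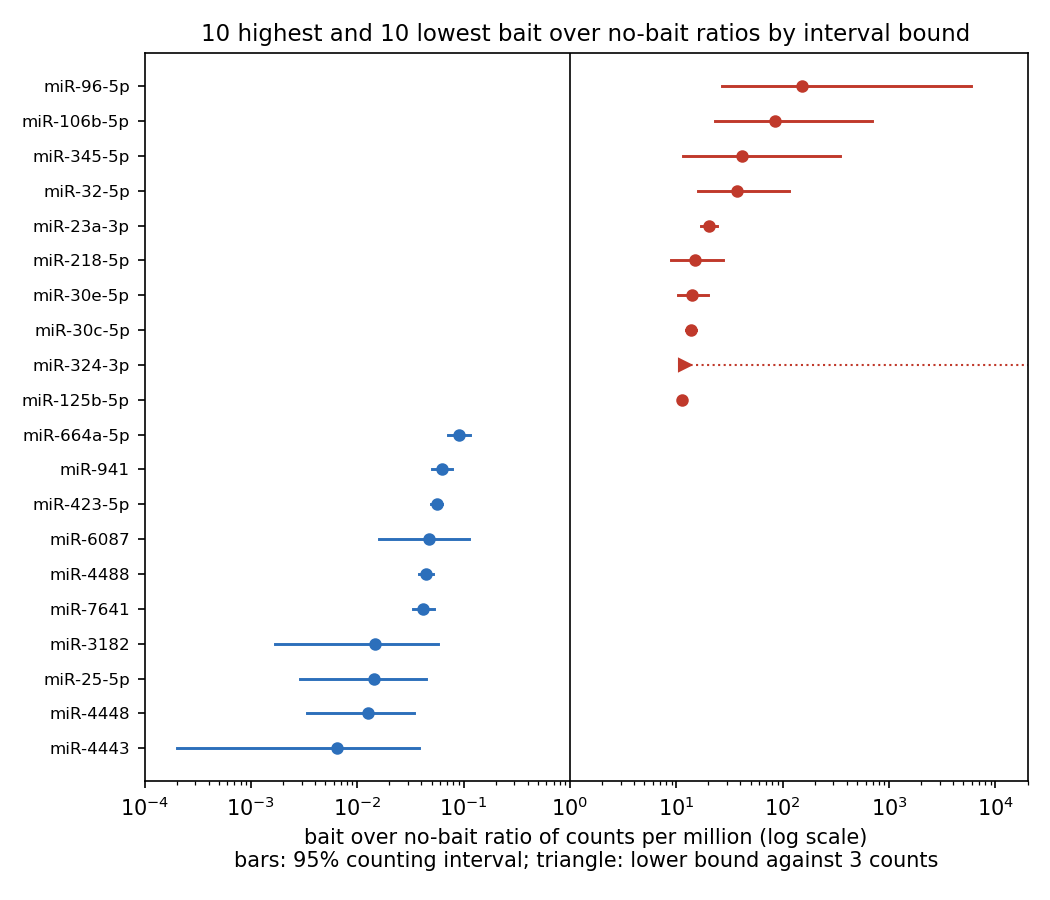
The x axis gives the bait over no-bait ratio of RPM on a log scale for the 20 miRNAs with the highest lower or the lowest upper interval bounds, each a row. Bars are 95% counting intervals. The triangle of miR-324-3p marks its ratio of 11.9 against the floor of 3 counts, and its 95% lower bound is 9.58. The intervals of miR-96-5p and miR-4443 are wide, since each had 1 count in 1 library.

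All 5 tested members of the miR-30 family were at least 2-fold higher with bait under each scaling, from 2.34-fold for miR-30d-5p to 14.1-fold for miR-30e-5p, and the list stood at the 97.8th percentile of random lists, its median log2 ratio of 2.65 level with the upper bound. Random lists hold mostly unrelated miRNAs, while members of 1 seed family varied less (SD of 0.77 against 1.68 in random groupings), so the percentile of a family list counts members as more independent than they are. Of 10 tested members of the miR-17-92 cluster and its paralogs, which are known from proliferating cells, 7 were higher and 1 was lower. The higher members included miR-20a-5p at 4.43-fold (3.27 to 6.15), and miR-92b-3p was 2.29-fold lower (2.18 to 2.40), a call that DESeq2 size factors ended. The ratio of miR-25-3p was 0.819, and 1.10 with DESeq2 size factors. This list lay at the 97.3rd percentile, inside the upper bound, and passed it at a minimum of 10 counts (98.5). Both tested members of the miR-29 family, known to target collagens, were higher, with miR-29a-3p at 5.999-fold (4.90 to 7.41) and miR-29b-3p at 3.13-fold (1.74 to 6.20). miR-16-5p, the tested member of the miR-15/16 family, was 8.49-fold higher (5.45 to 13.98). In the miR-181 family 2 of 3 were higher, and 3 with DESeq2 size factors (percentile 87.4), with miR-181a-5p at 8.32-fold and miR-181b-5p at 5.35-fold, and the ratio of miR-181d-5p was 2.01 with an interval of 0.791 to 6.53. In the miR-23-27-24 clusters 3 of 5 were higher (percentile 83.6). miR-27a-3p was 3.01-fold higher, while miR-24-3p and miR-27b-3p passed neither rule at ratios of 1.98 and 1.68. TMM added miR-24-3p at 2.20, for 4 of 5 higher, and DESeq2 size factors both, for 5 of 5.

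Other families went in both directions. Of 9 let-7 miRNAs 2 were higher and 2 lower (percentile 14.6). let-7g-5p was 2.14-fold higher (2.03 to 2.26), a call lost with totals that leave out the 5 most abundant miRNAs, and let-7i-5p was 2.73-fold lower (2.63 to 2.83). let-7f-5p and let-7a-5p had ratios of 0.624 and 0.618. In the group of miR-10, miR-99, miR-100 and miR-125, 1 of 7 was higher and 2 were lower (percentile 13.9). The member that rose was miR-125b-5p, and miR-10a-5p was 2.61-fold lower (2.51 to 2.72), although DESeq2 size factors left 0 lower members. Of 8 miRNAs of basal breast lines 2 were higher and 1 lower (percentile 64.8), and 4 were higher with DESeq2 size factors. The tumour-suppressor list had 3 higher of 5, or 4 with DESeq2 size factors (percentile 77.6). The higher members included the endothelial miR-126-3p at 3.31-fold (2.47 to 4.52) and miR-193b-3p. The ratio of miR-193b-3p was 7.47 against the floor of 3 counts, and the lower bound of its interval was 5.95. miR-143-3p had a ratio of 0.788, and 1.06 with DESeq2 size factors.

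All 4 tested members of the miR-320 family were lower under each scaling, from 3.62-fold for miR-320a (3.19 to 4.11) to 5.49-fold for miR-320c (3.33 to 9.16). Their sequences are nearly identical, and how shared reads were counted is unknown. The list lay at the 2.74th percentile. In the imprinted 14q32 cluster 3 of 4 were lower, with miR-127-3p 2.76-fold lower from 69 and 49 counts (ratio 0.363, 0.248 to 0.534) and miR-381-3p at 0.541 (0.244 to 1.29) from 21 and 10 counts. The other lower members also lay close to the count filter. They were miR-493-5p with 22 and 14 counts (0.405, 0.198 to 0.855) and miR-409-3p with 19 and 12 (0.408, 0.188 to 0.921). Random lists do not allow for the shared locus of these members. The list stood at the 0.575th percentile, which was 7.54 without matching on abundance. Its matched random lists centred on a log2 ratio of 1.02, above the median of 0.55 of all tested miRNAs. DESeq2 size factors left 1 lower member in this cluster. Entries that overlap other small RNAs, a sign of RNA fragments in a library, were all lower, 10 of 10 under each scaling (percentile 0.150). They held 0.132% of counts with bait and 1.06% without. miR-4485-3p, annotated in an exon of MTRNR2L8, was 5.65-fold lower and miR-1246 3.96-fold lower. At a minimum of 100 counts the percentile of this list was 3.56. In all, 3 of 12 lists with enough members stood apart.

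**Figure D3:**
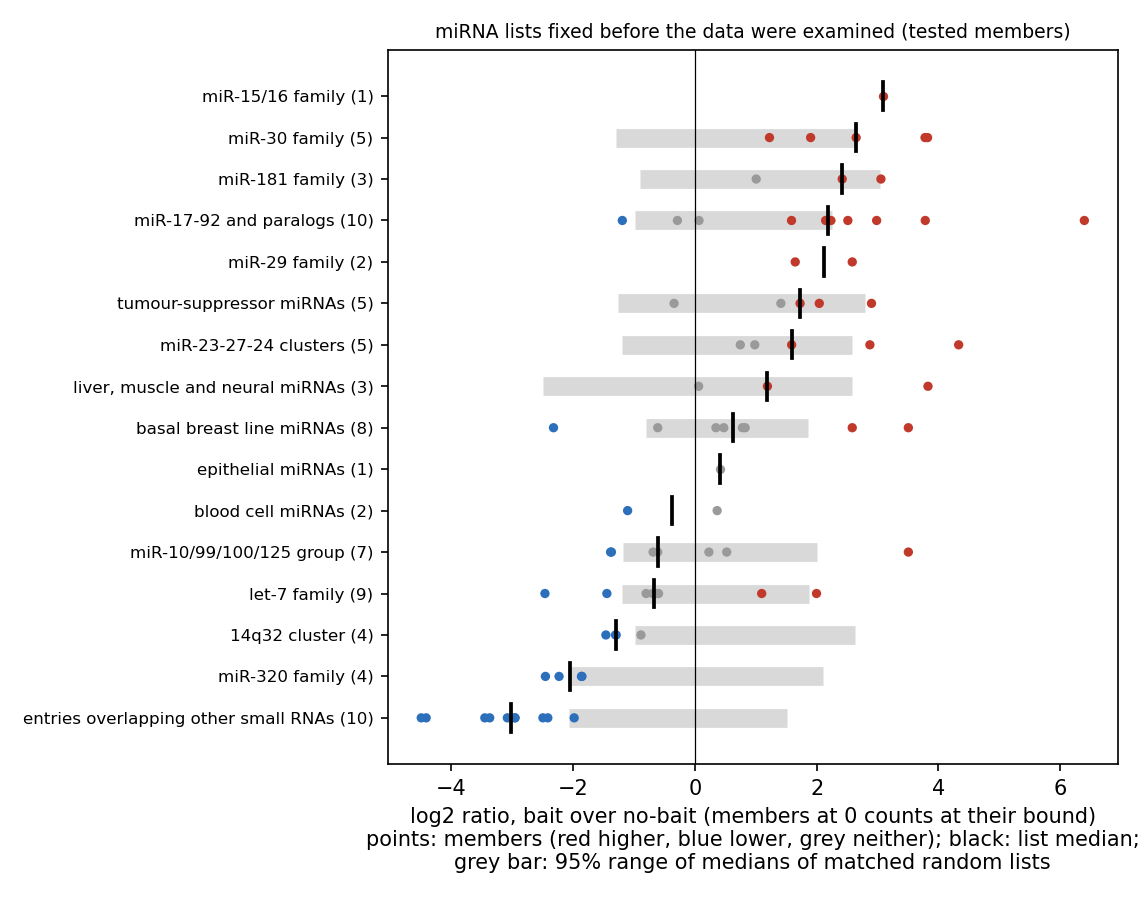
The x axis gives the log2 ratio of bait over no-bait for the tested members of each list, with the number tested in parentheses on the y axis. Points are members, black marks are list medians and grey bars hold 95% of the medians of matched random lists. The medians of the miR-30 family (2.65), the 14q32 cluster (-1.30) and the entries overlapping other small RNAs (-3.02) lie at or beyond their bars.

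Among markers of other cell types, the blood cell list took 0.0432% of counts with bait and 0.0864% without, and the liver, muscle and neural list 0.267% and 0.171%. The share of the latter lay mostly in miR-128-3p (1632 counts with bait and 403 without), miR-138-5p (938 and 17) and miR-9-5p (195 and 22). No other member of that list exceeded 14 counts with bait or 9 without, so its share does not show other cell types. Of the 2 tested blood cell members, miR-486-5p was 2.15-fold lower (ratio 0.465, 0.392 to 0.552), a call lost with TMM and DESeq2 factors, and miR-142-5p had a ratio of 1.29 (0.622 to 3.00). The epithelial list had 1 tested member, miR-200b-3p, at 1.32 (0.879 to 2.06). The liver, muscle and neural list had 2 higher of 3 (percentile 79.5), with miR-138-5p 14.2-fold higher (8.83 to 24.5) and miR-9-5p 2.28-fold higher (1.47 to 3.73), beside miR-128-3p at 1.04, or 0.954 without the 5 most abundant miRNAs. No member of the 19q13 primate cluster reached 30 counts, and the cluster held 17 counts with bait and 1 without.

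The miRNAs recalled as partners of MACC1-AS1 were too rare to test. miR-384 had 0 counts in both libraries, with 95% upper limits of 3.52 RPM with bait and 13.7 RPM without. miR-145-3p had 6 counts with bait and 3 without, a ratio of 0.515 (0.110 to 3.18). miR-145-5p had 4 and 1, a ratio of 1.03 (0.102 to 50.7). They were recalled from publications that may rest partly on the same libraries, so they are not an independent list.

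Both arms were tested for 34 hairpins. The minor arms had a median log2 ratio of 0.42, at the 17.5th percentile of random lists, so they did not stand apart. The median of the major arms was 0.50, a difference of -0.07 between the medians. Within hairpins the median difference of minor from major arm was -0.53, and the minor arm had the smaller ratio in 21 of 34. The difference between the medians was -0.63 at a minimum of 10 counts (58 hairpins) and -0.96 at 100 counts (15 hairpins). In 3 hairpins the arms were called in opposite directions, and these were named after their values were seen. miR-27a-3p was higher while miR-27a-5p was lower, 22.8-fold apart. The arms of miR-10a were 17.2-fold apart, with the 3p arm higher, and those of miR-361 7.11-fold apart, with the 5p arm higher. With DESeq2 size factors miR-27a alone of these kept opposite calls, and miR-27b and miR-423 gained them. Under scaling by totals, wider gaps lay in hairpins with 1 arm called. The arms of miR-106b were 107-fold apart, with the 5p arm higher. Those of miR-25 were 57.2-fold and those of miR-423 28.3-fold apart, with the 5p arm lower. In each of them the 3p arm passed neither rule.

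In the authors' deposited table, 143 miRNAs had a p-value under 0.05, of which 87 had positive and 56 negative fold changes. In that table the test is not named, and with 1 library per group it compares the libraries rather than the conditions. Of the 143, 118 were tested here, and all 118 were among the 153 called miRNAs in the same direction as in the authors' deposited table. Both rest on the same counts, so the direction was bound to match and is no independent check. The fold changes of the authors' deposited table differed from the ratios computed here by at most 0.01 on the log2 scale for the 412 miRNAs seen in both libraries.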

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

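Counting identical mature sequences once, leaving out the entries overlapping other small RNAs, and thinning the bait library were chosen after the data were seen, and the other alternatives before. The median ratio of 1.46 was 1.62 with TMM, 1.96 with DESeq2 size factors and 1.33 with totals without the 5 most abundant miRNAs, which follows from the changed factor. A minimum of 100 counts left 59 higher and 37 lower miRNAs of 146 tested. A minimum of 10 counts gave 95 higher and 81 lower of 325, and no count filter 95 and 100 of 715. The filter sums raw counts, and the bait library was 3.88-fold deeper, so miRNAs low with bait were dropped more readily. The excess of higher over lower calls therefore depended in part on the filter. All other settings kept both counts within 1.5 times the main ones, including thinning (86 higher and 58 lower) and the left-out small RNA entries (91 and 52). The miR-17-92 list passed the upper bound at 10 counts (98.5), with no count filter (99.3) and without matching (98.9), and the miR-320 list passed the lower bound without matching (2.46) but lay at 7.68 at 10 counts and 8.93 with no count filter. The 14q32 list was at 7.54 without matching and the entries overlapping other small RNAs at 3.56 at 100 counts, where fewer members are tested. The liver, muscle and neural list went from 79.5 to 43.9 at 10 counts, with more members tested. For the lists and percentiles the cause was not tested otherwise. Counted with the miR-320 values at 10 counts and with no count filter, 61 alternative values of the main results kept their direction and their side of the threshold or size. For single named miRNAs 70 alternative values moved beyond the counting interval. The log2 difference between the medians of minor and major arms grew from -0.07 to -0.63 at 10 counts, -0.96 at 100 counts and -0.76 with no count filter, while the minor arms lay at percentiles 55.3, 9.38 and 48.9 and never stood apart. For miRNAs with seed sites the log2 difference of 1.76 fell to 0.92 at 100 counts (percentile 68.6, 4 miRNAs) and to 1.21 with 6mers (95.7, 21 miRNAs). Sites of the 8mer kind were too few, and lower count filters were not run because sequences were written only for miRNAs with at least 30 counts. No paired analysis was possible because each group holds 1 library, which also rules out leaving out a replicate.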

Other observations

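All tests in this part were chosen after the data were seen, except the planned comparison of miRNAs with seed sites. The bound of the thinning test was set before its value was seen. The wording of the seed-family pattern was reversed after its value was seen: it was first written as members moving apart, and the data showed the opposite on average. The test of the small RNA entries with high-numbered miRNAs replaced one that only restated the list, and then left out the 10 miRNAs with the lowest upper bounds, both after values were seen.

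Members of neighbouring hairpins, which are often cut from 1 primary transcript, were in places far apart. In the cluster of miR-183, miR-96 and miR-182 on chromosome 7, the ratio was 0.351 for miR-183-5p (0.317 to 0.389), 1.44 for miR-182-5p (1.34 to 1.55) and 150 for miR-96-5p, a range of 428-fold that rests on 1 no-bait count of miR-96-5p. In the X-linked pair of miR-224 and miR-452, miR-224-5p was at 0.471 (0.428 to 0.520) and miR-452-5p at 20.9 (7.08 to 102). miR-425-5p and miR-191-5p on chromosome 3 were close, at 4.24 and 5.48. Over 18 such clusters with hairpins within 10000 bp of each other, the mean SD of log2 ratios was 1.56 and that of random groupings 1.70, at the 21.7th percentile, so no similarity of neighbours was resolved. Each hairpin entered with 1 arm, such as miR-106b-3p (0.787) and not miR-106b-5p (84.3). miR-92a-3p, which has more than 1 annotated hairpin, was left out. The percentile can depend on these choices.

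Many miRNAs were at least 2-fold apart between the libraries. When the bait library was thinned to the no-bait total, 91.2% of the 153 called miRNAs kept their call. Most calls therefore did not rest on the extra counts of the bait library. Thinning leaves each ratio the same on average and used the same tested miRNAs. It cannot weigh an effect of the shallow no-bait library or of the count filter. Against GC content the tables are mixed: after the linear GC trend was removed, 75.2% of the called miRNAs with a sequence were still at least 2-fold from the trend in their direction, compared with 88.6% before, and the trend took up 13.1% of the variance. Of the 90 higher miRNAs with a sequence, 86.7% had no site of 6 or more bases in the annotated transcript. Seed pairing with that transcript could not have raised those directly. The share says little more about pairing, since 199 of the 220 sequences had no such site. Of the 21 miRNAs with a site 12 were higher and 4 lower, against 78 and 55 of the 199 without. For the 5 miRNAs with a 7mer-m8 or 8mer site pairing stays open: their median log2 ratio was 1.76 above the others at percentile 95.4, but 0.92 at percentile 68.6 at a minimum of 100 counts, with miR-18a-5p, miR-193b-3p and miR-210-3p higher and miR-143-3p and miR-4326 not called. Too few sites, 1 library per group and an unknown bait isoform keep it open, and a part played by GC content cannot be told apart from the groups.

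Entries overlapping other small RNAs were low with bait. The tables argue against GC content as the cause, since the list stayed at percentile 0.085 after the GC trend of the other miRNAs was removed. A larger share of fragments of other RNAs in the no-bait library stays open: 7 tested miRNAs numbered 3000 or above outside the list, which are more often doubtful annotations, had a median log2 ratio of -0.79 at percentile 4.80 (26.6 after the GC trend was removed), with 3 lower and 1 higher. That leaves out miR-4443, miR-4448, miR-3182 and miR-7641, seen to be low before the test was chosen, with which the percentile was 0.010. Whether the fragments come from the resin, the lysate or the library preparation was not tested.

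Members of 1 seed family had similar ratios, with a mean within-family SD of log2 ratios of 0.77 in 26 families of 73 miRNAs, against 1.68 in random groupings. Reads shared between near-identical miRNAs do not seem to be the whole cause, since members more than 2 mismatches apart still lay at percentile 1.76, although their SD rose to 1.14 against 1.57. Families with no site of 6 or more bases in the annotated transcript were at percentile 0.0 (SD 0.82), so their similarity did not need pairing with it. Removal of the GC trend also left percentile 0.0 (SD 0.77). Both tests kept near-identical members, whose shared reads could hold their ratios together. Neither was run on members more than 2 mismatches apart, so they cannot weigh pairing or GC content where reads are not shared. A candidate explanation is a property of the sequence shared beyond the seed, in binding or in library preparation, and it was not tested. Exceptions were wide, with miR-32-5p and miR-92b-3p 85.2-fold apart, miR-106b-5p and miR-93-5p 28.1-fold, let-7b-5p and let-7c-5p 22.0-fold, miR-125b-5p and miR-125a-5p 7.91-fold and miR-221-3p and miR-222-3p 6.36-fold.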
